A study of Mus musculus with 6 samples.

How the data were processed

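Total RNA of the 6 cultured fibroblast samples was extracted with an RNeasy kit, and libraries were made with Illumina TruSeq v2 reagents, per the labels' protocols. Reads were aligned with STAR to mm10 and handled with DESeq2, per the submitters' processing notes. The gene annotation, the read counter, its strand setting, the versions and any filters are not given in the sources used here. Reads of a gene and of an antisense or near-identical partner could therefore not be told apart.

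The deposited table holds a signal per gene and library, which has the form of read counts divided by 1 size factor per library. Every value was a whole multiple of the value of 1 read in its library (100% of values within 0.001), so whole reads were recovered. The value of 1 read ran from 0.732 to 1.21 normalised counts. The table has 27179 rows keyed by Entrez gene number, of which 93.0% matched the GRCm38 RefSeq table. Of 6263 rows with no name, 4376 were given a RefSeq symbol, and 26 symbols that had turned into dates were restored by their number. Rows without a name held 1.90% to 2.23% of reads and carry gene numbers, so they stayed in the tests. The 10 genes with most reads took 3.35% to 4.50% of reads per library.

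The test fixed before the data were examined was edgeR for counts, with limma on log2 values as the stated fallback for values divided by size factors. The deposited unit called for the fallback. Genes were kept by filterByExpr with a minimum of 10 in 3 libraries, which left 14777. Limma 3.58.1 (trend and robust) in R 4.3.3 was run on log2(value + 1) for the 3 knockout against the 3 control libraries, two-sided, with Benjamini-Hochberg adjustment and an FDR of 0.05. Fold changes from limma are on the log2(value + 1) scale, which understates the change of low genes. DESeq2 1.42.0 and edgeR 4.0.16 (quasi-likelihood, TMM) were run on the recovered reads as alternatives, and adjusted p-values that DESeq2 left blank stayed blank. Each library had a guide of its own, so the libraries came from separately infected and selected cells, and the spread behind each p-value includes differences between guides. The labels do not say whether these cells shared a starting culture. A check for a library deposited more than once found no pair that agreed within sampling noise (chi-square per degree of freedom from 17.9 to 524.9).

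Of 34 gene lists fixed before the data were examined, 31 with at least 5 tested members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. A further 6 lists were chosen after seeing the data and are described by counts, medians, quartiles and means per library, with no p. Named genes were fixed by rule as Zmat3, the 10 largest rises and 10 largest falls among genes past the FDR with a mean of at least 50 and no overlap between groups, up to 4 members per list, and Trp53, Mdm2, Mdm4, Cdkn1a and Cd44. Because limma called no gene, the part of the rule that needs calls was applied to DESeq2's calls, a choice made after limma's result was seen.

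Each test was tried on simulated reads drawn from the real means, library sizes and dispersions, with 200 of 14777 genes changed by known folds. Depth ran from 53253055 to 90256118 reads per library. Alternatives changed the test, scaling, filter, pseudocount, threshold, replicate block and the libraries used. The trend on GC content and length came from the longest GENCODE transcript of each symbol in GRCm38.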

Results

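RNA sequencing was carried out on mouse embryonic fibroblasts that expressed Cas9, an adenoviral E1A oncogene and an activated Hras oncogene. Guide RNAs were brought in by lentivirus, cells with guides were selected, and RNA was collected after 10 days of culture. The 6 libraries formed 2 groups of 3, a control group with negative control guides and a knockout group with guides against Zmat3. Each library had a guide of its own, and the knockout guides were numbered 52.6, 51.5 and 54.8 for libraries 1, 2 and 3. The comparison addressed which transcripts differ when Zmat3, a p53-induced gene for a zinc finger RNA-binding protein, is targeted. The control libraries held 81027772, 90256118 and 60730974 reads assigned to genes, and the knockout libraries 69515101, 55383299 and 53253055. All values below are normalised read counts, given as mean ± SD with n = 3 libraries per group.

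Zmat3 (Entrez gene 22401) lies on the minus strand of chromosome 3 in GRCm38, from position 32334792 to 32366014, and its annotated transcript with most exons has 7. Its transcript was lower in every knockout library than in any control library. The mean normalised count was 16824 ± 838 (SD, n = 3) in control and 7097 ± 3744 (SD, n = 3) in knockout. The knockout libraries stood at 67.9%, 29.2% and 29.5% of the control mean in libraries 1, 2 and 3, so library 1 retained most transcript. The log2 fold change was -1.36 (SE 0.33), with an adjusted p of 0.371 in limma. DESeq2 gave -1.24 (SE 0.34) with an adjusted p of 0.0444. Without control library 3 the limma log2 fold change was -1.34, while DESeq2's adjusted p was 0.21. The limma adjusted p lay between 0.121 and 0.624 when 1 library was left out. An exact two-sided permutation test of the 6 values gave p = 0.1, which is the smallest p that 3 libraries against 3 allow. Frame-shifting edits by Cas9 need not lower a transcript, so the level does not measure the share of edited cells.

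**Figure D1:**
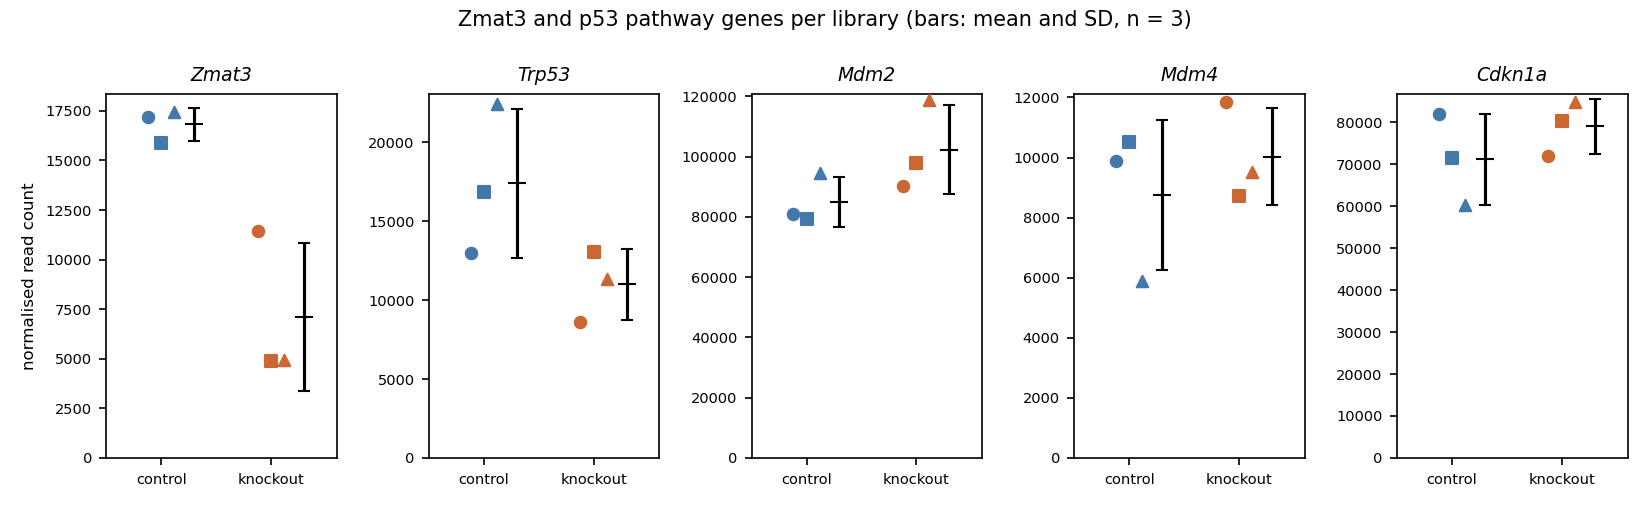
Normalised read counts (y axes from 0) of Zmat3, Trp53, Mdm2, Mdm4 and Cdkn1a in each control (blue) and knockout (orange) library, with circles, squares and triangles for libraries 1, 2 and 3 and bars for the mean and SD. Zmat3 stood at 67.9%, 29.2% and 29.5% of the control mean in the 3 knockout libraries, and the other 4 genes passed no test.

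Some genes of amino acid uptake and synthesis were called lower in the Zmat3 knockout libraries by DESeq2, and none by limma over all genes. In a wider list of 32 amino acid response genes chosen after seeing the data, DESeq2 called 15, all lower, while 6 members had positive log2 fold changes. That list also holds genes outside uptake and synthesis, such as Chac1, Trib3 and Atf5. Slc7a5, a subunit of a transporter of large neutral amino acids, stood at 26070 ± 3960 (SD, n = 3) in control and 9938 ± 1059 in knockout. Shmt2, a mitochondrial enzyme of serine and folate metabolism, stood at 27958 ± 5532 and 9532 ± 1181. Chac1, an enzyme that degrades glutathione, stood at 2764 ± 628 and 757 ± 184, and Asns, which makes asparagine, at 20792 ± 3657 and 10128 ± 274. Among genes above control, Slfn8 rose from 106.8 ± 25.5 to 542.4 ± 296.6 and Atf3, a stress-induced transcription factor, from 1744 ± 219 to 3961 ± 897, both by DESeq2's test.

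The number of genes called depended on the test. The test fixed for values already divided by size factors, limma on log2 values, called 0 of 14777 genes at an FDR of 0.05, with 1948 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.331. On the recovered whole reads edgeR also called 0 genes, with 1943 at an unadjusted p under 0.05, whereas DESeq2 called 129, of which 61 were higher and 68 lower in knockout. In simulated reads with 200 changed genes among 14777, 76 of DESeq2's 207 calls were false, against 3 of limma's 105, so single DESeq2 calls are held less firmly. Limma recovered 24% of the 2-fold changes and 84% of the 4-fold changes in that simulation, and DESeq2 recovered 60% and 96%. With dispersions 4 times lower limma recovered 78% and 98% and DESeq2 82% and 100%, and 14 of limma's 179 and 55 of DESeq2's 234 calls were false. Each gene was simulated independently, whereas many genes of a real library shifted together, as in control library 3 below. The simulated rates therefore need not hold for the real reads. "Rose" and "fell" below refer to DESeq2's calls unless another test is named. Of the 125 DESeq2 calls that limma also tested, 122 had 3 knockout libraries entirely outside the range of the 3 control libraries. Over all 14777 genes, 4067 (27.5%) were separated in this way, with 1946 higher and 2121 lower in knockout. The share expected for interchangeable libraries is 10%. Genes of the same library move together, so the share of a single split can lie far from 10% by chance, and the excess was not tested.

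Control library 3 stood apart from the other 5. The first principal component held 59.4% of the variance and separated it from the rest, and its mean correlation with the other libraries was 0.941 against 0.969 to 0.975 for the others. Without it, limma called 5 genes and DESeq2 711, and 113 of the 129 DESeq2 calls were among those 711, all in the same direction. The direction could hardly differ, because 122 of the 125 calls that limma also tested had no overlap between groups. The 5 limma calls were Asns, Mthfd2, Slc7a5 and Shmt2, lower in knockout, and Cyr61, higher in knockout, all named after their values were seen. Cyr61, an early response matrix protein, stood at 94991 in control library 3 against 7831 and 7553 in control libraries 1 and 2. Its knockout level was 14684 ± 556 (SD, n = 3). The limma log2 fold change of Cyr61 was -0.28 over all 6 libraries and 0.93 without control library 3. Hoxd11, Sim2 and Hras, named after their values were seen, also set control library 3 apart. Hoxd11 stood at 9.44 there against 981 to 1221 in the other libraries. Sim2 stood at 1668.5 against 5.86 to 97.0, and Hras at 9789 against 3125 to 5117. Leaving out other libraries moved the DESeq2 count to 2138 (control 1), 86 (control 2), 61 (knockout 1), 24 (knockout 2) and 27 (knockout 3).

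**Figure D2:**
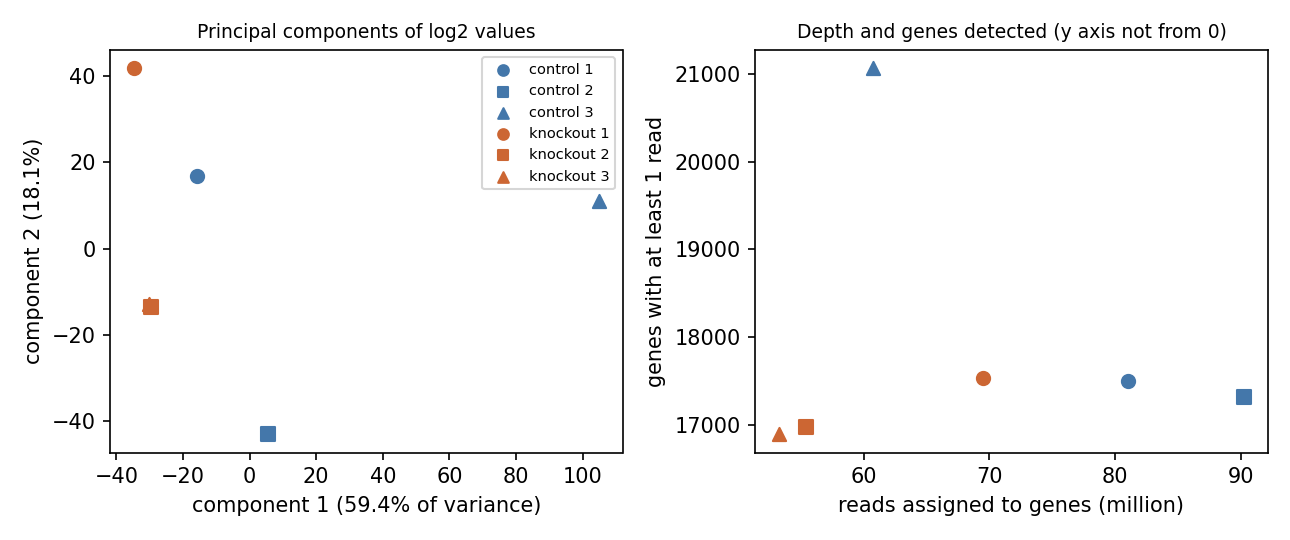
Left, the first and second principal components of log2 values over 14777 genes, with the share of variance on each axis; right, genes with at least 1 read against reads assigned to genes, with a y axis that does not start at 0. Control library 3 lay alone on the first component and had reads in 21067 genes, against 16889 to 17530 in the other 5 libraries.

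The 10 largest rises by the fixed rule, applied to DESeq2's calls because limma made none, were in Srgn, D430019H16Rik, Ebf4, Slc14a1, Cpne7, Mdk, Slfn8, Atp8b1, Camkv and Tmem40. Srgn, the proteoglycan serglycin, rose from 6.29 ± 5.78 to 93.7 ± 41.8 (SD, n = 3), a DESeq2 log2 fold change of 3.89 (SE 0.73, adjusted p = 0.000111). Its values in control libraries 1, 2 and 3 were 12.7, 1.46 and 4.72, so few control reads lie behind this change. Slc14a1, a urea transporter, rose from 32.4 ± 17.8 to 199.6 ± 68.0, and Mdk, the growth factor midkine, from 326.7 ± 241.8 to 1734 ± 749. The limma log2 fold change of Mdk was 2.82, and 1.85 without control library 3. Camkv, a kinase-like protein of neurons, rose from 163.3 ± 86.4 to 734.7 ± 319.2. The DESeq2 log2 fold changes of the other named rises ran from 2.02 for Tmem40 to 3.27 for D430019H16Rik. P2rx7, an ATP-gated ion channel, was named after its values were seen because it had the smallest DESeq2 adjusted p, 4.92e-10, with 92.5 ± 7.3 in control and 336.0 ± 42.0 in knockout.

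The 10 largest falls by the same rule were in Xylt1, Nkx2-5, Gdap1, Sprr1a, Chac1, Rrp12, Pop1, Shmt2, Mybbp1a and Slc7a5. Xylt1, which starts glycosaminoglycan chains, fell from 120.4 ± 108.6 to 4.93 ± 2.29 (SD, n = 3). Nkx2-5, a cardiac transcription factor, fell from 136.1 ± 113.3 to 6.70 ± 5.85, and Gdap1 from 153.0 ± 203.9 to 8.91 ± 3.91. The control libraries of these 3 genes differed widely, with 120.6, 11.7 and 228.9 for Xylt1. Sprr1a, a cornified envelope precursor, fell from 1578 ± 914 to 419 ± 150. Without control library 3 the calls of Nkx2-5 (DESeq2 adjusted p = 0.176) and Sprr1a (DESeq2 adjusted p = 0.201) were lost, and DESeq2 gave no adjusted p for Xylt1 and Gdap1. The limma log2 fold changes went from -4.18 to -3.83 for Nkx2-5, from -1.76 to -1.35 for Sprr1a, from -3.66 to -2.81 for Xylt1 and from -3.07 to -1.91 for Gdap1. Rrp12, Pop1 and Mybbp1a, which act in ribosomal RNA or tRNA processing and nucleolar transcription, had DESeq2 log2 fold changes of -1.77, -1.69 and -1.51, and control library 3 held the highest value of each. Without it the limma log2 fold changes went from -1.52 to -0.94 for Rrp12, from -1.49 to -0.94 for Pop1 and from -1.30 to -0.75 for Mybbp1a.

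In the fixed list of unfolded protein and integrated stress response genes, 7 of 20 members were called by DESeq2, 6 lower and Atf3 higher. Without control library 3 DESeq2 called 7 lower and 3 higher. Chac1 had a DESeq2 log2 fold change of -1.87 (SE 0.28, adjusted p = 7.8e-08), Asns -1.04 (SE 0.19) and Phgdh, the entry enzyme of serine synthesis, -1.23 (SE 0.28). Adjusted over the list alone, limma called 13 of the 20 members, 8 lower and 5 higher. The higher members included Ddit3 and Xbp1 and the lower ones Atf4, at limma log2 fold changes of 0.85, 0.51 and -0.53, named after their values were seen. The value for Atf4 was -0.31 without control library 3. The chaperone Hspa5 stood at 80758 ± 12794 in control and 80656 ± 10241 in knockout (SD, n = 3). The list passed fry's test for change in either direction (adjusted p = 0.000155) and not its test for movement one way (adjusted p = 0.177), and its camera adjusted p was 0.0545, and 0.012 without control library 3. With an estimated correlation the adjusted p was 0.541, and 0.575 without that library. Slc7a11, the cystine transporter subunit, fell by 0.96 and Txnip, an inhibitor of thioredoxin, rose by 1.29 on the log2 scale in the list of oxidative stress genes, whose mean and median differed in sign (0.0017 and -0.22, with a median of -0.06 without control library 3).

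**Figure D3:**
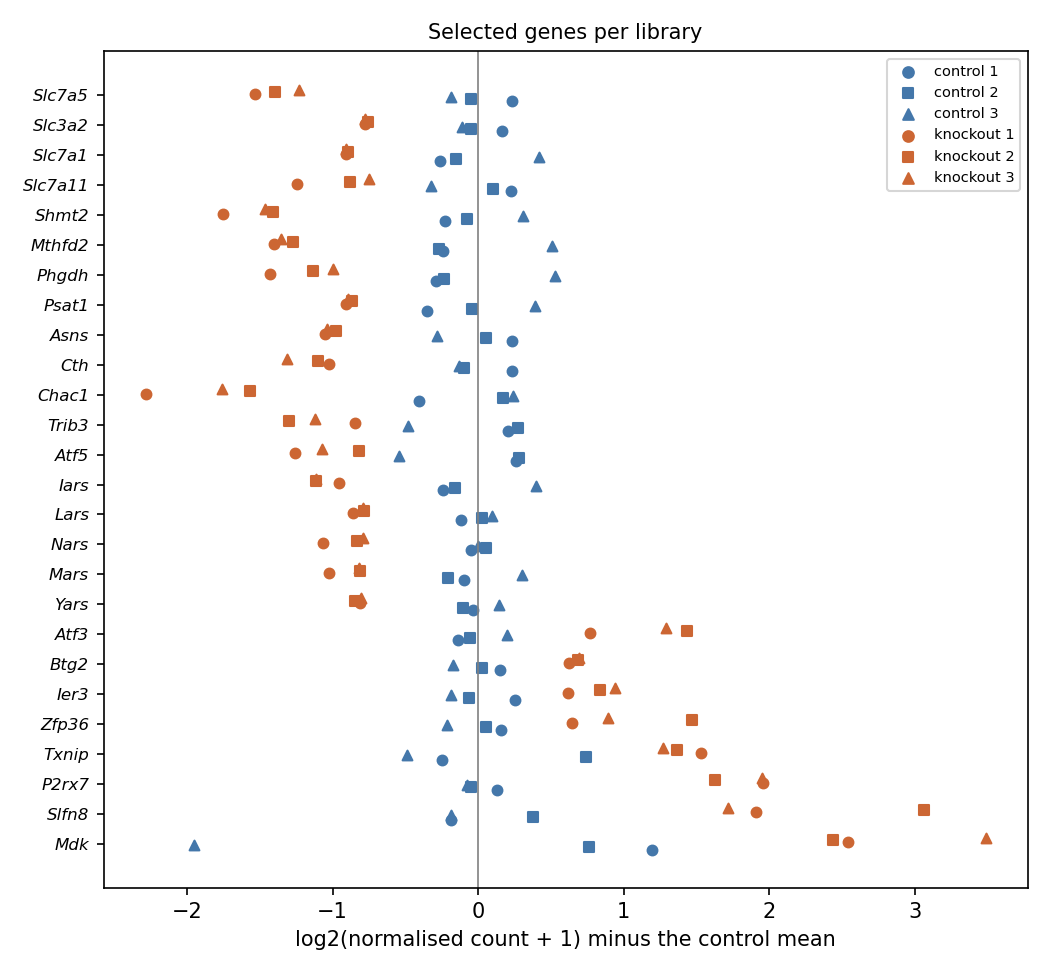
Log2(normalised count + 1) minus the control mean for 26 genes, chosen after their values were seen, in each control (blue) and knockout (orange) library; circles, squares and triangles are libraries 1, 2 and 3. The 3 knockout libraries lay outside the range of the 3 control libraries for each gene shown.

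Cell cycle genes were lower in knockout as a group. All 24 members of the mitosis list had negative log2 fold changes, with a median of -0.64, and all 30 of the DNA replication list, with a median of -0.40. Without control library 3 these medians were nearer to zero, at -0.44 for mitosis and -0.31 for DNA replication. Camera with a preset correlation of 0.01 gave adjusted p-values of 8.91e-13 and 2.22e-09, and with an estimated correlation the adjusted p was 0.541 for each. Over all genes no mitosis member was called by limma or DESeq2, and without control library 3 DESeq2 called 12 mitosis and 4 DNA replication members, all lower. Adjusted over the list alone limma called 15 of 24, all lower. Mki67, a marker of dividing cells, stood at 20573 ± 3095 in control and 12094 ± 2232 in knockout (SD, n = 3). Fen1, a flap endonuclease of DNA replication, fell from 8410 ± 2226 to 4399 ± 792 by DESeq2, and Lmnb1, a nuclear lamin in the senescence list, from 12167 ± 1979 to 7391 ± 773. The mean of the mitosis list lay 0.45 above the control mean in control library 3 and 0.35 below it in control library 1, on the log2 scale.

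Genes of RNA metabolism were mostly lower. Of 40 splicing factors, 38 had negative log2 fold changes with a median of -0.33. Their camera adjusted p was 1.32e-07, and 0.541 with an estimated correlation. None was called by limma or DESeq2. Without control library 3 their median was -0.22 and DESeq2 called 2, both lower. Mbnl1, a splicing regulator, stood at 7928 ± 1647 in control and 5142 ± 302 in knockout. Among 23 genes that bind AU-rich elements or degrade RNA, 19 were negative with a median of -0.19, and -0.14 without control library 3. Over all libraries their camera adjusted p was 0.0125, and 0.541 with an estimated correlation. The list also passed fry's test for change in either direction, with an adjusted p of 0.0309. Its only member called by DESeq2, Zfp36, which binds AU-rich elements and promotes RNA decay, rose from 4410 ± 574 to 9044 ± 2763 (SD, n = 3). Without control library 3 more lists passed fry's test for change in either direction. Among them were matrix genes (fry adjusted p = 0.00135) and p53 targets (fry adjusted p = 0.0175). Lists of unlike kinds passed too, such as ribosomal proteins (fry adjusted p = 0.0351), neural markers (fry adjusted p = 0.0289) and leukocyte markers (fry adjusted p = 0.0326). Passing this test therefore did not set matrix genes or p53 targets apart.

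Early response genes, many of which carry AU-rich elements, were higher. Of 25 members, 19 had positive log2 fold changes with a median of 0.45, and DESeq2 called 5, all higher, and 9 without control library 3. Btg2, an antiproliferative p53 target, rose from 9764 ± 1082 to 15460 ± 410, Ier3 from 3865 ± 634 to 6691 ± 746, and Atf3 had a DESeq2 log2 fold change of 1.19 (SE 0.24, adjusted p = 0.000544). Adjusted over the list alone, limma called 6 members, all higher. Camera gave an adjusted p of 0.000146, and the adjusted p was 0.541 with an estimated correlation.

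Neither list of p53 genes passed camera. Of 40 p53 targets 28 had positive log2 fold changes, with a median of 0.15 and a camera adjusted p of 0.14, and DESeq2 called Btg2 higher and Zmat3 lower. That median was 0.08 without control library 3, where DESeq2 called 4 targets, all higher. Trp53 stood at 17420 ± 4728 in control and 11014 ± 2253 in knockout (SD, n = 3), a limma log2 fold change of -0.65 (SE 0.24, adjusted p = 0.371). Mdm2, the ubiquitin ligase that restrains p53, had 0.26 (SE 0.15), Cdkn1a, a cell cycle inhibitor, 0.16 (SE 0.15) and the adhesion receptor Cd44 0.23 (SE 0.12). Mdm4, a relative of Mdm2, had 0.23 (SE 0.24). With 1 library left out, Mdm2 ran from 0.15 (without knockout library 3) to 0.35, Cdkn1a from 0.04 (without control library 3) to 0.27 (without control library 1), and Mdm4 from -0.03 (without control library 3) to 0.38 (without control library 2). None of these 5 genes passed limma, edgeR or DESeq2. The 14 regulators of p53 had a median of -0.09 (camera adjusted p = 0.376), with the smallest p in Chek1, at -0.61. Gene counts do not resolve exons, so splicing of Mdm4 or Cd44 was not analysed here.

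Extracellular matrix, adhesion and lysosome genes were above control by camera, each without a call when the correlation was estimated (adjusted p = 0.541). The medians were 0.52 for matrix genes (camera adjusted p = 0.0229), 0.59 for metalloproteinase and adhesion genes (0.00504), 0.48 for growth factor genes (0.0137), 0.33 for lysosome genes (0.0137) and 0.54 for antigen presentation genes (0.00577). Efemp1, a matrix glycoprotein, rose from 7.87 ± 5.78 to 84.9 ± 25.04 and was the only member of these lists that DESeq2 called. Without control library 3 these medians were 0.24 for matrix genes, 0.28 for metalloproteinase and adhesion genes, 0.12 for growth factor genes, 0.18 for lysosome genes and 0.31 for antigen presentation genes. The camera adjusted p of growth factor genes was then 0.1, and DESeq2 called 3 matrix genes but gave no adjusted p for Efemp1. Timp1, an inhibitor of metalloproteinases, stood at 28783 ± 11649 in control and 62890 ± 17023 in knockout (SD, n = 3).

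Interferon response genes varied between libraries of the same group. The median of 30 genes was 0.77 (camera adjusted p = 0.022; adjusted p = 0.71 with an estimated correlation) and -0.04 without control library 3. On the log2 scale the list's mean stood 0.39, 1.53 and -1.92 from the control mean in control libraries 1, 2 and 3, and -0.69, 1.79 and 1.75 in knockout libraries 1, 2 and 3. Control library 3 was also lowest in antigen presentation genes, at -0.86, in fibroblast markers, at -0.66, and in leukocyte markers, at -1.11.

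**Figure D4:**
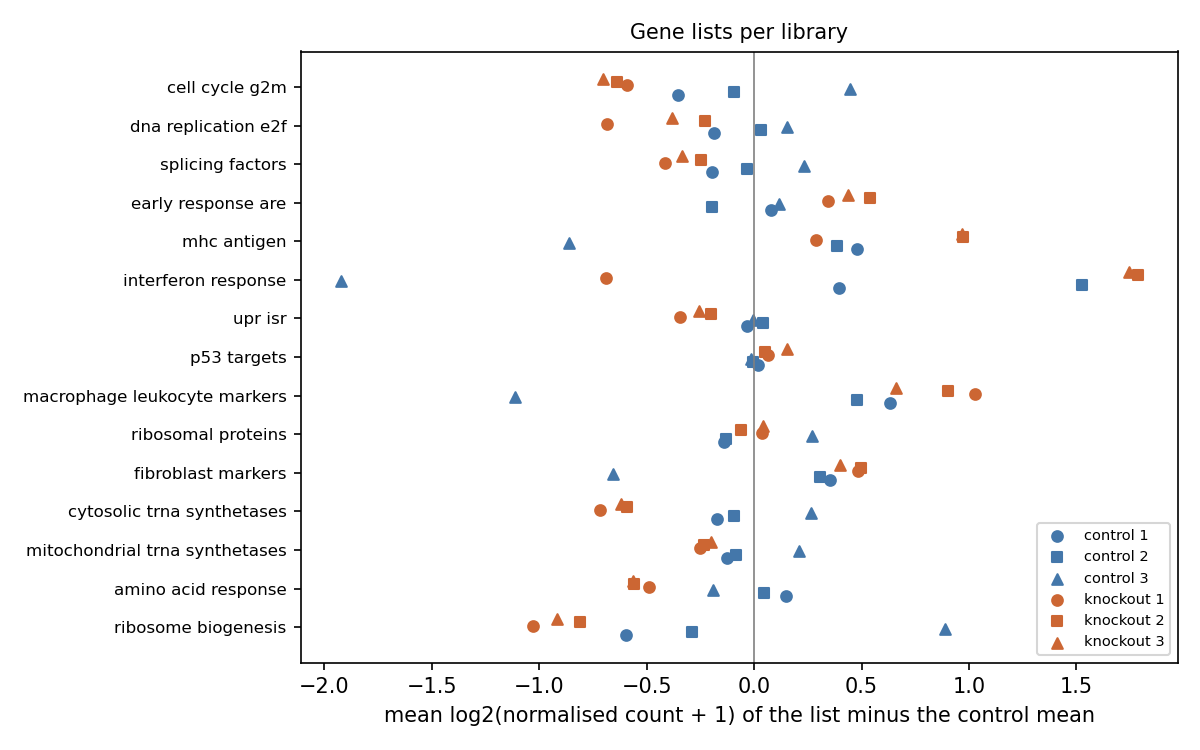
Mean log2(normalised count + 1) of 15 gene lists minus the control mean in each control (blue) and knockout (orange) library, with circles, squares and triangles for libraries 1, 2 and 3; the lists of tRNA synthetases, amino acid response and ribosome biogenesis genes were chosen after seeing the data. The interferon list ran from -1.92 in control library 3 to 1.79 in knockout library 2.

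The other fixed lists did not pass camera. The medians were 0.05 for ribosomal proteins, -0.09 for oxidative phosphorylation, -0.11 for cholesterol synthesis, 0.28 for MAP kinase output, 0.53 for inflammatory genes, 0.08 for apoptosis, -0.10 for tumour suppressors, 0.43 for the senescence list and -0.09 for the Zmat family. Glycolysis genes had a median of 0.05 while their mean and camera's direction were negative. Myofibroblast genes had a median of 0.06. Without control library 3 the median was 0.16 for ribosomal proteins, which then passed camera (adjusted p = 0.000277; adjusted p = 0.575 with an estimated correlation). It was 0.02 for cholesterol synthesis and -0.0013 for oxidative phosphorylation, both with camera's direction turned to higher. It was -0.04 for the Zmat family, 0.11 for myofibroblast genes, 0.01 for glycolysis, 0.17 for MAP kinase output, 0.01 for apoptosis and 0.24 for the senescence list. Markers of other cell types had medians of 1.00 (leukocytes, 5 genes tested), 0.68 (epithelium, 10), 0.59 (neural, 7) and 0.87 (fat and cartilage, 11), and fibroblast markers 0.34 (12). Without control library 3 these were 0.35 for leukocyte, 0.19 for epithelial, 0.24 for neural, 0.23 for fat and cartilage and 0.11 for fibroblast markers. Endothelial markers, muscle markers and genes whose splicing is linked to Zmat3 had under 5 tested members and were not tested.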

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

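Of the alternatives in this part, those chosen after seeing the data were edgeR on the recovered reads (planned only for a table of counts), TMM scaling, and all alternatives to the DESeq2 counts. With limma, 0 genes and 0 list members were called under quantile normalization, recomputed size factors, upper quartile and TMM scaling, no trend, both pseudocounts, both filters and the replicate block. DESeq2 called 129 genes (61 higher, 68 lower) and 17 list members, and the Zmat3 log2 fold change there was -1.24. Without each replicate in turn limma called 0 to 5 genes (0 to 1 higher, 0 to 4 lower) and 0 to 2 list members; the 5 genes came without control replicate 3. The DESeq2 counts ran from 24 to 2138 without each replicate, with 9 to 1036 higher and 14 to 1102 lower. All 129 calls kept the sign of their log2 fold change in each of these fits, and 20 to 124 of them were called again. The kept signs say little, because 122 of the 125 calls that limma also tested had no overlap between groups. Leaving out 1 library could hardly turn such a sign. DESeq2 called 218 genes (136 lower) at a mean of 50 or more, 37 (15 higher, 22 lower) at an FDR of 0.01, 245 (106 higher, 139 lower) at 0.1, and 79 (32 lower) with an absolute log2 fold change of at least 1.

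With the replicate block, DESeq2 called 559 genes (311 higher, 248 lower), 118 of them among the 129. Same-numbered libraries correlated at 0.264, 0.199 and -0.017 in their deviations, so the numbers were not taken to pair the libraries, and knockout library 3 did not correlate best with its own number. With an estimated correlation 0 lists passed, and with fry's test for movement one way 0, against 11 with the preset. Fry's test for change in either direction passed 2 lists. Of 58 named genes compared over 12 settings, 1 reversed, Mdm4, at -0.0346 without control replicate 3 (up to 0.38 without other replicates), and the interferon list's median was -0.0351 without it (up to 1.67). Genes named for having no overlap between groups could hardly reverse when 1 library was left out. Cyr61, not among the 58, turned from -0.28 to 0.93 without control replicate 3. The cause of these changes was not tested. Scaling moved the median log2 fold change of all genes to at most 0.08. Alternatives on deposited adjusted p-values or base means were not run, since the table used here has no such columns. For genes with many reads the spread between libraries, not counting error, set the precision. Genes with few reads in 1 group, such as Srgn and Efemp1 in control, also carry counting error.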

Other observations

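The lists of amino acid response, synthetase, ribosome assembly, chaperone and YAP target genes, and the tests of control library 3 alone, growth state, RNA of another cell type, unedited cells and other splits, were chosen after the results were seen. A p for those lists would restate how they were chosen, so none is given for them. The tests on GC content and length and on genomic DNA were written before their results were seen. The readings of growth state in amino acid response genes, RNA of another cell type and unedited cells were set to open after their values were seen, because spread, low reads or an assumption kept them from deciding.

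Of 32 amino acid response genes, DESeq2 called 15, all lower in knockout. They included the transporter subunits Slc3a2 (19402 ± 1953 in control and 11340 ± 76 in knockout, SD, n = 3) and Slc7a1 (11572 ± 3089 and 6053 ± 30), the folate enzyme Mthfd2 (10920 ± 3572 and 4167 ± 190), and Psat1, Cth, Trib3 and Atf5. The median log2 fold change was -0.59, and 6 members were positive. Of 20 cytosolic tRNA synthetases, which load amino acids onto tRNAs, DESeq2 called 11, all lower, with Lars at 19568 ± 1471 and 11125 ± 317 and Nars at 30753 ± 1081 and 16564 ± 1673. Their median was -0.69. The 17 mitochondrial synthetases had a median of -0.19 (-0.105 without control library 3) and no call, and the 18 ER chaperone genes -0.17. The difference between the cytosolic and mitochondrial lists was not tested. Of the 68 genes DESeq2 called lower, 26 belonged to the amino acid response and cytosolic synthetase lists, and all 26 were called again without control library 3. The share of 26 partly restates how the lists were chosen. In that fit 113 of all 129 calls recurred, on libraries already used.

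The 30 ribosome assembly genes were all negative, with a median of -0.97, and DESeq2 called Mybbp1a, Tcof1 and Rrp12. Without control library 3 the median was -0.52 and DESeq2 called 16 of them, all lower. Their mean lay 0.89 above the control mean in control library 3 and 0.60 and 0.29 below it in control libraries 1 and 2, on the log2 scale. The 16 YAP target genes had a median of -0.21, and -0.05 without control library 3.

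The lower amino acid response and cytosolic synthetase genes, 52 in all, had a median log2 change of -0.69. The median was -0.58 without control library 3 (quartiles -0.80 and -0.28), so the lower level of these genes did not rest on that library alone. The genes were chosen for being lower in these same libraries, so this value is a description and not a test of a cause. After taking out the trend on GC content and length the median was -0.78 (quartiles -0.98 and -0.45). The trend held only 1.5% of the variance of log2 changes over genes, so taking it out could move the median little and decides nothing. A growth state may account for part of the synthetase change, though growth was not measured. Control library 3, highest in ribosome assembly genes, lay 0.39 above the other controls in synthetases (quartiles 0.12 and 0.62). This rests on 1 library that also differed in other ways. The synthetase median was -0.69 with that library and -0.60 without it. For amino acid response genes the median of control library 3 against the other controls was -0.16 with quartiles -0.67 and 0.36, so growth state stays open there. A response to Zmat3 loss, which the design names, stays open as a hypothesis.

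Control library 3 had reads in 3037 of 8065 genes with no read in the other 5 libraries, against 55 to 128 such genes for each other library, and in 388 of 1122 olfactory receptor genes against 8 to 16. These 9446 reads were 0.0156% of the library. Genomic DNA could give such reads: olfactory receptor genes carried 0.359 times the reads per kilobase of the other such genes, between the bounds set for and against it. RNA of another cell type could also do so, and the 10 genes with most held 6.55% of these reads, but the median gene had 2 reads, too few to decide. No other explanation of these reads was tested.

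Knockout library 1 kept 67.9% of the control level of Zmat3. Unedited cells could be the source if they made up 54.5% of that library. This share takes knockout libraries 2 and 3 as fully edited and all guides as lowering the transcript alike, neither of which was shown. It predicts the 52 genes above to stand 0.42 higher than in knockout libraries 2 and 3 on the log2 scale. The observed median was -0.0415 (quartiles -0.24 and 0.16). The prediction also assumes that these genes follow Zmat3, which was not shown, so the explanation stays open, as does a different effect of the guide on the transcript.

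The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. DESeq2 called 129 genes for the real split and at most 102 for another, so the real split was the only 1 of the 10 with that many. Limma called 0 in the real split and 0 at most in another, so all 10 had to give as many and this count says nothing about chance; genes at an unadjusted p under 0.05 numbered 1948 in the real split and at most 834 in another.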
